A study of Mus musculus with 12 samples.

How the data were processed

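RNA from 12 mouse uteri was measured on Illumina expression bead arrays, 1 array per uterus. The labels describe female C57BL/6 mice that were genotyped and necropsied at 2 months of age, and place 3 uteri in each of 4 genotypes: wild type, knock-out of Cdh1, knock-out of Trp53 and knock-out of both genes. The groups are named here control, Cdh1 cKO, Trp53 cKO and double cKO, with the ending that the titles carry. Uterine tissue was homogenised in Trizol, and the RNA was cleaned on columns, checked on a Bioanalyser, and amplified and labelled with biotin, per the labels' protocols. The recombinase, the deleted exons, the stage of the estrous cycle and the chip that held each array are not given in the sources used here.

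The authors deposited a table of non-normalized intensity per probe and array, with a detection p-value for each intensity, the number of beads behind it and a bead standard error, per the file headers. The 12 columns of bead standard errors were not used here. The deposited detection p-values stepped in units that imply 936 negative control probes. The authors also deposited a matrix of processed log2 values of the same arrays, whose background correction and normalization are not given in the sources used here. Limma 3.10.2 is named in the submitters' processing notes. The median of every matrix column was 4.72 on the log2 scale, and its values differed from those computed here by at most 0.0234 and by a median of 3.79e-04, so its scale is settled by the comparison and it holds no ratio and no centring on genes.

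The intensities were background corrected, quantile normalised and put on a log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, which took the background from the detection p-values and added an offset of 16. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Gene symbols and the order of genes along chromosomes came from the RefSeq genes of assembly GRCm38.p6, which held the gene of 99.8% of the probes with 1 symbol. Probes with a detection p below 0.05 on at least 3 of the 12 arrays were kept, which left 23229 probes, of which 19680 had 1 symbol. For each gene the probe with the highest mean was used, which gave 12194 genes, and 4975 of these had more than 1 detected probe. For some of the named genes, the differences given by other detected probes stand beside them.

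A limma model with a coefficient per group was fitted to all 12 arrays, so that the groups shared 1 estimate of the spread on 8 residual degrees of freedom with a prior of 2.84. The model was moderated with eBayes, and 6 contrasts were taken: each ablated group against control, the double cKO against each single cKO, and the interaction, which is the double cKO minus the Cdh1 cKO minus the Trp53 cKO plus control. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 12194 genes, and a gene was called at an adjusted p below 0.05 with no minimum fold. Every adjusted p of a gene comes from this limma model. Errors beside log2 differences are the standard errors of the model, and errors beside group means are standard deviations. A gene whose probe was not detected on all 3 arrays of the dimmer group has only a bound there. Its fold is then written as at least the mean of the brighter group over the mean, per array, of the higher of the probe's own value and the lowest signal among detected probes, with the adjusted p of the model. Such a bound takes in the dim signal only, not the spread between arrays.

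The genes to be named, the tests, the gene lists and most alternatives were fixed before the data were examined. Named are Cdh1 and the 10 largest rises and 10 largest falls among called genes whose 3 values in each group did not overlap. For the double cKO against single cKO and for the interaction these are 5 and 5, for the interaction without the condition on overlap. Up to 4 members of each list described, those with the smallest adjusted p, are named too. The rule also held Trp53, which was not analysed here. Members named as not passing are those with the highest mean in their list. Predicted genes and genes with clone names are counted and not named, and where few genes passed, all are named. Genes named outside this rule are said to be so.

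The 35 gene lists were written from textbook knowledge of the uterus, p53, E-cadherin and immune cells, and cover junctions, epithelia, hormone responses, stroma, muscle, vessels, immune cell types, secreted mediators, and tissues that a dissection could bring along. They hold 945 entries, of which 882 had a probe. Of these lists 34 had at least 5 tested genes, and the ovary list was too short to be tested. Each was tested with camera at a preset correlation of 0.01 between genes, 2-sided, adjusted over the 34 lists of a comparison. The test was repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move on balance in 1 direction. Single members were counted at an adjusted p over all genes and adjusted over the list alone. Some genes belong to several lists.

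Samples of 1 number in the titles were checked for pairing. The deviations from the group means of same-numbered control and Cdh1 cKO arrays correlated at 0.218 to 0.332. Each array correlated best with its own number, so these numbers were treated as possibly pairing the arrays. No label states what a number stands for. The other pairs of groups showed no such pairing, and same-numbered Cdh1 cKO and Trp53 cKO arrays correlated at -0.648 to -0.207. With so few arrays and several pairs of groups checked, 1 such match may arise by chance.

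The steps were tested on simulated data. For the double cKO against control with 200 of 12194 genes changed in each of 20 runs, the model recovered 1.80% of genes changed by 0.5 on the log2 scale, 38.9% at a change of 1, 88.3% at 2 and 98.3% at 4, and 5.88% of its calls were false. An unchanged comparison gave 0.2 calls per run. A list shifted by 0.5 was called in 20 of 20 runs, and 3 of 660 tests of other lists were called. The genes were simulated independently of one another, so these list results do not cover correlation between the genes of a list.

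Alternatives covered the background correction, the normalization, the matrix of processed values, the filter on dim probes, every named probe in place of 1 per gene, the moderation of the variance, array weights, the arrays in the model, the replicate number as a block, a minimum fold, and each array left out in turn. A score of estrogen response genes as a covariate, and the block on only 6 arrays, were added after the data had been seen. Trp53 itself was not analysed here, and chip effects were not tested because no chip is given.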

Results

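Expression was measured in 12 uteri from 2-month-old female mice, 3 each from control mice and from mice with ablation of Cdh1, of Trp53 or of both. Cdh1 encodes E-cadherin, the cell adhesion protein of epithelial adherens junctions, and Trp53 encodes the tumour suppressor p53. Between 44.3% and 47.9% of the 45281 probes were detected on each array, which is 20075 to 21670 probes. The median intensity per array lay between 106 and 119, and a median of 41 to 43 beads stood behind each probe. Across probes, arrays of a group correlated with r between 0.936 and 0.987, and arrays of different groups with r between 0.920 and 0.979. The uteri labelled Cdh1 cKO were the least alike, with r between 0.936 and 0.945. Their replicates 1, 2 and 3 each correlated more with a Trp53 cKO array, at 0.966, 0.974 and 0.961. Control replicate 3 and Trp53 cKO replicate 2 also correlated most with an array of another group, at 0.979 and 0.970. The number of arrays per group limits the precision, and the p-values measure the spread between these uteri. No label states whether any of the uteri came from littermates.

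The targeted genes come first. The brighter Cdh1 probe had a mean log2 signal of 9.73 ± 0.34 (SD, n = 3) in control, 9.77 ± 0.20 in the uteri labelled Cdh1 cKO, 9.14 ± 0.11 in Trp53 cKO and 8.41 ± 1.17 in double cKO. The control uteri had 9.71, 9.41 and 10.08, and the uteri labelled Cdh1 cKO had 9.74, 9.58 and 9.98. The double cKO uteri spread widely, with 9.67, 8.18 and 7.36. The first of these, replicate 1, also had the oviductal glycoprotein gene Ovgp1 at 13.20, where the others had 5.43 and 5.79 and the control uteri 10.39 to 11.95, and the medians of ciliated and oviduct genes on the 3 double cKO arrays were 1.14, -0.14 and -0.35. Against control, Cdh1 differed by 0.03 ± 0.45 (SE) in the uteri labelled Cdh1 cKO (adjusted p = 0.990) and by -1.33 ± 0.45 in double cKO (adjusted p = 0.154). Without double cKO replicate 1, the Cdh1 difference of double cKO from control was -1.96 and that from the uteri labelled Cdh1 cKO was -1.99, and both passed (adjusted p = 0.00699 and 0.0126). Without double cKO replicate 2 or 3, the difference from control was -1.22 or -0.80 (adjusted p = 0.282 and 0.394). That from the uteri labelled Cdh1 cKO was then -1.25 or -0.84 (adjusted p = 0.657 and 0.922), and none of these passed. In Trp53 cKO the difference was -0.59 ± 0.45 (adjusted p = 0.9995). A dim second probe of Cdh1 differed from control by -0.21, -0.08 and 0.30 in the same order of groups. The Cdh1 signal did not separate the uteri labelled Cdh1 cKO from control, and since the deleted exons are not given in the sources used here, these probes do not check the genotype. Trp53 was not analysed here.

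**Figure D1:**
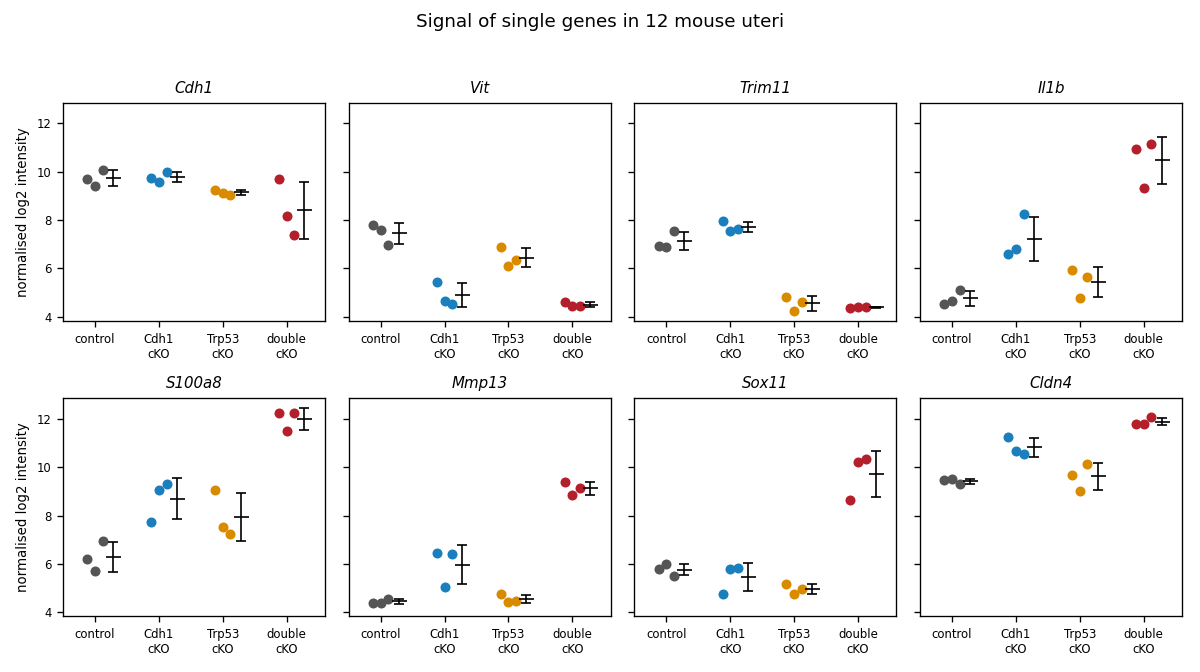
Log2 signal of 8 genes on each array (points), with the mean and SD of the 3 arrays of each group. Il1b, S100a8, Mmp13, Sox11 and Cldn4 were highest in double cKO, Trim11 was lowest in the 2 groups with Trp53 ablation, and Cdh1 was as high in the uteri labelled Cdh1 cKO as in control.

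Ablation of Cdh1 alone addresses what loss of E-cadherin does to the uterus. Vit, which encodes the extracellular matrix protein vitrin, was at least 5.20-fold lower (adjusted p = 0.0423), from a log2 signal of 7.45 ± 0.44 (SD, n = 3) in control to one detected on 1 of 3 arrays of the uteri labelled Cdh1 cKO, in which Cdh1 itself was not lower. It was the only gene called. The genes next in order of p did not pass. Among them were Atg9b, an autophagy gene, at 4.10 ± 0.55 (adjusted p = 0.0806), the interleukin 1 receptor antagonist Il1rn, at least 3.08-fold higher (adjusted p = 0.1204), the proprotein convertase gene Pcsk6 at 2.35 ± 0.36 (adjusted p = 0.133), the endocytic receptor gene Lrp2, at least 28.9-fold lower, and the stress gene Nupr1 at 1.55 ± 0.26 (both adjusted p = 0.157). Other probes of these genes gave smaller differences, 1.15 for Atg9b, 0.48 for Il1rn and -0.24 for Lrp2.

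As groups, macrophage genes had a median log2 difference of 0.57 in the uteri labelled Cdh1 cKO against control, with 32 of 34 genes above 0 (camera adjusted p = 4.47e-09, and adjusted p = 0.255 with an estimated correlation). Neutrophil genes had a median of 0.66 (adjusted p = 9.59e-07, and 0.119 with an estimated correlation), and 9 of 23 were higher and 1 lower when adjusted over the list alone. Cytokines and their receptors had a median of 0.36 (adjusted p = 1.41e-05, and 0.0918 with an estimated correlation), with 8 of 31 genes higher when adjusted over the list alone. Genes of the uterine epithelium had a median of 0.52 (adjusted p = 1.41e-05, and 0.285 with an estimated correlation), and immediate early genes, which tissue handling can raise, had a median of 0.52 with 17 of 17 above 0 (adjusted p = 2.52e-05, and 0.119 with an estimated correlation). Genes of squamous epithelium had the largest median, 1.41, or 1.16 with dim genes at their bound (adjusted p = 5.09e-05, and 0.355 with an estimated correlation). That median came from 1 uterus, since the list's array medians were -0.56, -0.59 and 2.26 in this group, and without replicate 3 the adjusted p was 0.276. Proliferation genes had a median of -0.66 with 35 of 37 below 0 (adjusted p = 1.57e-04, and 0.588 with an estimated correlation), and without control replicate 3, whose proliferation and epithelium genes were the highest of the control group, the adjusted p was 0.322. Single arrays also moved medians that stayed called. Without control replicate 3 the median was 0.32 for macrophage genes and 0.87 for epithelium genes, and the latter was 0.29 without control replicate 1 and 0.32 without Cdh1 cKO replicate 3. Without Cdh1 cKO replicate 1 the proliferation median was -0.37, and without its replicate 2 it was -1.03, with the squamous median at 2.31. No member of any list passed over all genes.

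In all, limma called 1 of 12194 genes, with 1070 at an unadjusted p below 0.05, where chance gives 610, and the 3 values per group did not overlap for 11.8% of genes, where chance gives 10%. Of 34 lists, 17 were called, none with an estimated correlation and 2 by fry. Without control replicate 3, 38 genes were called, without Cdh1 cKO replicate 2 there were 11 and without its replicate 1 there were 2, while 0 were called without control replicate 1, control replicate 2 or Cdh1 cKO replicate 3. Replicate numbers may pair the arrays of these groups. With the replicate number as a block 1 gene was called, or 0 in a model of only these 6 arrays.

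Ablation of Trp53 alone addresses what loss of p53 does to the uterus. Trim11, a ubiquitin ligase gene, was at least 4.76-fold lower (adjusted p = 8.07e-04), from a log2 signal of 7.13 ± 0.37 in control to the background on all 3 arrays. The clone-named gene 4933427D14Rik was at least 7.65-fold lower (adjusted p = 8.07e-04). These were the only genes called, and both were also low in double cKO. The inflammatory caspase gene Casp4 differed by -1.20 ± 0.25, the membrane protein gene Pllp was at least 2.56-fold lower and the Ttc27 gene at least 8.78-fold higher, none of which passed (adjusted p = 0.9995). For Ttc27 the control arrays had 4.52, 4.71 and 8.27 and the Trp53 cKO arrays 8.92 to 9.33. Its fold thus rests on control replicates 1 and 2. Other probes of Casp4 differed by -0.58 to -0.51.

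Among gene groups, interferon response genes had a median of 0.50 in Trp53 cKO, with 29 of 32 above 0 and 1 higher when adjusted over the list alone (adjusted p = 5.23e-11). Proliferation genes had a median of 0.69, with 36 of 37 above 0 (adjusted p = 1.07e-09). Their array medians were 0.80, 0.53 and 0.76 in Trp53 cKO and -0.42, -0.36 and 0.74 in control, so that control replicate 3 lay at the level of Trp53 cKO. Without that array the median was 1.12, and without Trp53 cKO replicate 3 the interferon median was 0.26. Neither call held with an estimated correlation (adjusted p = 0.764 with an estimated correlation for both). Genes that respond to progesterone had a median of -0.25 (adjusted p = 0.00812, and 0.764 with an estimated correlation), and without control replicate 1 or Trp53 cKO replicate 2 this call was lost, with an adjusted p of up to 0.188, while without control replicate 3 the median was -0.49. The p53 targets had a median of -0.11, with 29 of 39 below 0, and did not pass (adjusted p = 0.0689). Limma called 2 genes, with 290 at an unadjusted p below 0.05, where chance gives 610, and 9.06% of genes did not overlap between groups, where chance gives 10%. Without control replicate 3, 9 genes were called. Of 34 lists, 7 were called, and 0 with an estimated correlation or by fry.

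Ablation of both genes addresses what their combined loss does. Il1b, which encodes the cytokine interleukin 1 beta, was at least 46.5-fold higher in double cKO than in control (adjusted p = 3.72e-04), with a log2 signal of 10.47 ± 0.98 (SD, n = 3) against one detected on 1 of 3 control arrays. S100a8 and S100a9, whose products form the calprotectin of neutrophils, rose 52.1-fold and at least 33.9-fold (adjusted p = 3.72e-04 and 4.60e-04). Chil1, which encodes a secreted chitinase-like protein, was at least 69.3-fold higher (adjusted p = 0.00785), and the wound keratin gene Krt17 rose by 5.25 ± 0.68 (adjusted p = 0.00242). Mmp13, which encodes a collagenase, was at least 19.2-fold higher (adjusted p = 6.24e-05), although its other detected probe differed by -0.02. Ppbp, a chemokine of platelets, was at least 21.8-fold higher (adjusted p = 0.00291). The other named rises were Ffar4, a fatty acid receptor gene, by 5.01 ± 0.83, Serpinb11, a serpin gene, at least 41.3-fold, and Trim15, at least 21.8-fold (adjusted p between 0.00539 and 0.0422), with the other probe of Trim15 at 1.003 on the log2 scale. Cdh1 itself did not pass in this group with all 3 arrays.

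Among the genes that fell, Vit was at least 6.07-fold lower (adjusted p = 4.89e-04) and Trim11 at least 4.86-fold lower (adjusted p = 1.40e-04). Bpifb5, of a family of secreted lipid-binding proteins, was at least 24.4-fold lower (adjusted p = 0.0194). Arsj, an arylsulfatase gene, fell by 2.94 ± 0.33 (adjusted p = 9.58e-04), with its other probe at -0.45, and Aard fell by 2.91 ± 0.39 (adjusted p = 0.00291). The angiopoietin-like gene Angptl7 and the lipogenic gene Thrsp were at least 20.2-fold and 14.1-fold lower. Wdr92 and the synapsin gene Syn2 were at least 6.93-fold and 5.14-fold lower, and Smim41 fell by 2.67 ± 0.59 (adjusted p between 0.0268 and 0.0478 for these last 5). The other probe of Wdr92 differed by -0.20 and that of Angptl7 by -2.98. In all, limma called 333 genes, 233 higher and 100 lower, and 280 of them differed by at least 1 on the log2 scale. At an unadjusted p below 0.05 there were 2082 genes, where chance gives 610, and 25.7% of genes did not overlap between groups, where chance gives 10%. The count moved with single arrays: 141 genes were called without control replicate 1, 117 without control replicate 2, 553 without control replicate 3, 194 without double cKO replicate 1 and 137 without double cKO replicate 3. Trim15 was no longer called without any 1 of these 6 arrays, Bpifb5, Angptl7 and Thrsp without any 1 but control replicate 3, Wdr92, Smim41 and Syn2 without either of control replicates 1 and 2, and Ffar4 without control replicate 2 or double cKO replicate 3.

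Neutrophil genes rose the most among the lists, by a median of 1.90, or 1.51 with dim genes at their bound. Of 23, 11 rose and 0 fell over all genes, and 16 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.18e-18, and 0.0121 with an estimated correlation). Clec4d, a lectin receptor of myeloid cells, rose at least 9.75-fold (adjusted p = 6.24e-05) and the formyl peptide receptor gene Fpr2 9.62-fold (adjusted p = 8.74e-04), whereas Ltf, which encodes lactoferrin and is also made by uterine epithelium, differed by 1.94 ± 0.84 and did not pass (adjusted p = 0.268), with its other probe at 3.63. Macrophage genes rose by a median of 1.26, with 15 of 34 higher over all genes and 30 adjusted over the list alone (adjusted p = 2.27e-27, and 0.0225 with an estimated correlation). Among them, Fcgr2b, an Fc receptor gene, rose 4.39-fold (adjusted p = 8.53e-04), with other probes at 0.32 to 2.01 on the log2 scale. The myeloid receptor genes Cd300lf and Lilrb4a were at least 2.59-fold and 2.54-fold higher (adjusted p = 4.42e-04 and 8.53e-04), while Laptm5 at 0.60 ± 0.26 and the complement gene C1qb at 1.23 ± 0.40 did not pass. Genes of alternatively activated macrophages rose by a median of 0.46, with 3 of 15 higher over all genes and 6 adjusted over the list alone (adjusted p = 5.48e-04, and 0.0230 with an estimated correlation), or 0.27 without control replicate 3. They included the chitinase-like gene Chil3, at least 2.32-fold higher (adjusted p = 0.0162) and with its other probe at a log2 difference of 0.98, and Tgfb1, which rose by 0.82 ± 0.17 (adjusted p = 0.0317), though both lost their calls without control replicate 1 or double cKO replicate 1 or 2. In contrast, the T and NK cell list had a median of -0.11 (adjusted p = 0.805) and the red blood cell list one of -0.41 (adjusted p = 0.962).

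Secreted mediators and proteases rose with the myeloid genes. Of 31 cytokines and receptors, 12 rose and 0 fell over all genes and 15 were higher adjusted over the list alone, with a median of 0.49 (adjusted p = 1.21e-10, and 0.0121 with an estimated correlation). Il1rn was at least 20.6-fold higher (adjusted p = 2.47e-05) and the tumour necrosis factor gene Tnf at least 2.86-fold (adjusted p = 4.60e-04), while Tnfrsf1b, a receptor for it, rose by 1.41 ± 0.18 (adjusted p = 0.00196). The other probes of Il1rn and Tnfrsf1b differed by 3.42 and 0.48 on the log2 scale. Of 29 chemokine ligands, 7 rose and 1 fell, and 10 were higher and 2 lower adjusted over the list alone (median 1.05, adjusted p = 4.66e-05, and 0.0194 with an estimated correlation). Ccl9 rose 8.05-fold (adjusted p = 8.53e-04), Ccl17 was at least 6.40-fold higher (adjusted p = 0.00118) and Ccl6 rose by 2.91 ± 0.47 (adjusted p = 0.00957). Of 24 genes of matrix remodelling, 7 rose and 0 fell, and 9 were higher adjusted over the list alone (median 0.89, adjusted p = 3.44e-07, and 0.0113 with an estimated correlation). The macrophage elastase gene Mmp12 was at least 9.83-fold higher (adjusted p = 5.91e-05), Adam8 rose at least 3.36-fold (adjusted p = 0.00344) and the cathepsin gene Ctss rose by 1.44 ± 0.20 (adjusted p = 0.00416), while the gelatinase gene Mmp2 differed by -0.56 ± 0.38 and did not pass (adjusted p = 0.514). Single arrays moved the medians of these called lists, to 0.81 or 0.74 for cytokines without control replicate 1 or 3, to 0.70 or 0.58 for chemokines without control replicate 2 or double cKO replicate 2, and to 0.55 for matrix remodelling without double cKO replicate 1. These 6 groups were the ones that held with an estimated correlation, out of 15 lists called, and fry called 12.

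**Figure D2:**
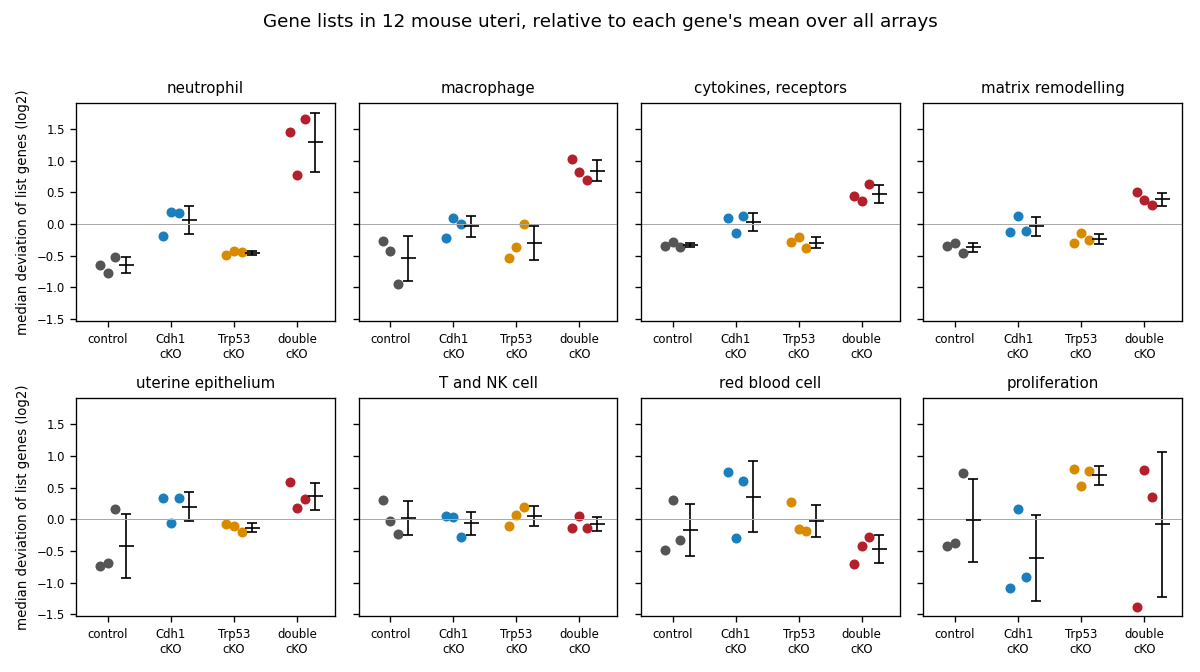
Median log2 deviation of 8 gene lists on each array (points), each gene taken from its mean over the 12 arrays, with the mean and SD of each group. The neutrophil, macrophage and cytokine lists were highest on the double cKO arrays, while the T and NK cell list lay near 0 in all groups.

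The claudin gene Cldn4, whose protein seals tight junctions, rose 5.53-fold in double cKO against control (adjusted p = 8.53e-04) and Cldn6 was at least 15.2-fold higher (adjusted p = 0.00356). As a list, 22 genes of tight junctions and desmosomes had a median of 0.77, with 2 higher over all genes and 10 adjusted over the list alone (adjusted p = 2.20e-08, and 0.0711 with an estimated correlation). Genes of the uterine epithelium had a median of 0.72, with 2 of 32 higher over all genes, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 1.57e-07, and 0.109 with an estimated correlation). The array medians of the tight junction list were 0.65, 0.16 and 0.30 in double cKO and -0.78, -0.62 and 0.02 in control. Those of the epithelium list were 0.59, 0.18 and 0.32 against -0.73, -0.68 and 0.17, so that control replicate 3 lay apart from the other controls in both lists. Without it the median of the epithelium list was 1.13. Wnt7b, a Wnt ligand of the luminal epithelium, rose by 2.86 ± 0.55 (adjusted p = 0.0229), with its other probe at 2.27. The adherens junction list, to which Cdh1 belongs, did not pass (median 0.30, adjusted p = 0.218), and the vascular cadherin gene Cdh5 in it fell by 1.11 ± 0.24 (adjusted p = 0.0331). Estrogen response genes had a median of 0.83, with 3 of 27 higher over all genes and 5 adjusted over the list alone (adjusted p = 0.00222, and 0.323 with an estimated correlation), or 0.32 without control replicate 1 and 0.52 without double cKO replicate 1, and the cornified envelope gene Sprr2g rose by 2.42 ± 0.40 (adjusted p = 0.0105). A score of 17 estrogen response genes held by no other list averaged 0.53 ± 0.42 (SD, n = 3) in double cKO and -0.61 ± 0.64 in control. With this score as a covariate, 171 genes were called, among them Cldn4 and Cldn6. Of the 63 genes named by rule or as list members for this comparison, 30 lost their calls. For the 18 of these detected on all 6 arrays, the difference was smaller in 17, between 60.6% and 115% of its size was kept, with a median of 74.9%, and the SE grew in 16, with its median going from 0.370 to 0.414. With the score the differences were 3.97 ± 0.96 for Ffar4, 2.41 ± 0.57 for Ccl6, 1.97 ± 0.57 for Wnt7b, 1.70 ± 0.38 for Sprr2g and 1.21 ± 0.35 for Egr2, where the model without it gave 5.01 ± 0.83, 2.91 ± 0.47, 2.86 ± 0.55, 2.42 ± 0.40 and 1.54 ± 0.29. Those of Smim41 and Cdh5 were -1.61 ± 0.56 and -0.74 ± 0.24, where it gave -2.67 ± 0.59 and -1.11 ± 0.24. Steap3 at -1.56 ± 0.35 differed by more than the -1.36 ± 0.28 without the score. Chil1, Trim15, Bpifb5, Angptl7, Thrsp, Wdr92, Syn2 and Chil3 also lost their calls, and since each was at background on at least 1 array, their sizes were not compared. Without control replicate 2, the calls of Wnt7b, Cdh5 and Sprr2g were lost, those of Wnt7b and Cdh5 also without control replicate 1 or any 1 of the double cKO replicates.

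Other immune lists were higher with calls that were lost with an estimated correlation. Interferon response genes had a median of 0.83 with 31 of 32 above 0, 1 higher over all genes and 5 adjusted over the list alone (adjusted p = 1.21e-10, and 0.255 with an estimated correlation). The array medians of that list were 1.18, 0.22 and -0.02 in double cKO and -0.43, -0.28 and -0.57 in control, and without double cKO replicate 1 the median was 0.55 (adjusted p = 5.10e-06). Genes of dendritic cells and MHC class II had a median of 0.76, with 2 of 17 higher over all genes and 8 adjusted over the list alone (adjusted p = 7.11e-07, and 0.109 with an estimated correlation), or 0.42 without control replicate 3, among them Cd40, which rose by 1.05 ± 0.24 (adjusted p = 0.0472). Complement genes had a median of 0.81, with 4 of 14 higher over all genes and 7 adjusted over the list alone (adjusted p = 2.62e-06, and 0.106 with an estimated correlation). C1qc and C1qa, which encode chains of the first complement component, rose by 1.29 ± 0.27 and 1.12 ± 0.26 (adjusted p = 0.0327 and 0.0483). Immediate early genes had a median of 0.69 with 2 of 17 higher over all genes and 5 adjusted over the list alone, led by Egr2 at 1.54 ± 0.29 with an adjusted p of 0.0212 (adjusted p = 8.50e-05 for the list, and 0.0711 with an estimated correlation). Endothelial genes had a median of -0.43, with 1 of 29 higher and 1 lower over all genes, and 3 higher and 7 lower adjusted over the list alone (adjusted p = 0.00944, and 0.551 with an estimated correlation). That call was lost without control replicate 1 or 2, with an adjusted p of up to 0.0752. The p53 targets had a median of -0.03 (adjusted p = 0.906), and the iron reductase gene Steap3 among them fell by 1.36 ± 0.28 (adjusted p = 0.0294), with its other probes near -0.10. The calls of Cd40, C1qc, C1qa, Egr2 and Steap3 were each lost without control replicate 2 and also without double cKO replicate 1 or replicate 3. Proliferation genes had a median of -0.06 (adjusted p = 0.962), with array medians of -1.37, 0.78 and 0.36 in double cKO. Without double cKO replicate 1 the proliferation median was 0.56 and passed (adjusted p = 6.58e-05), and without its replicate 2 the median was -0.49 and passed (adjusted p = 0.0320).

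**Figure D3:**
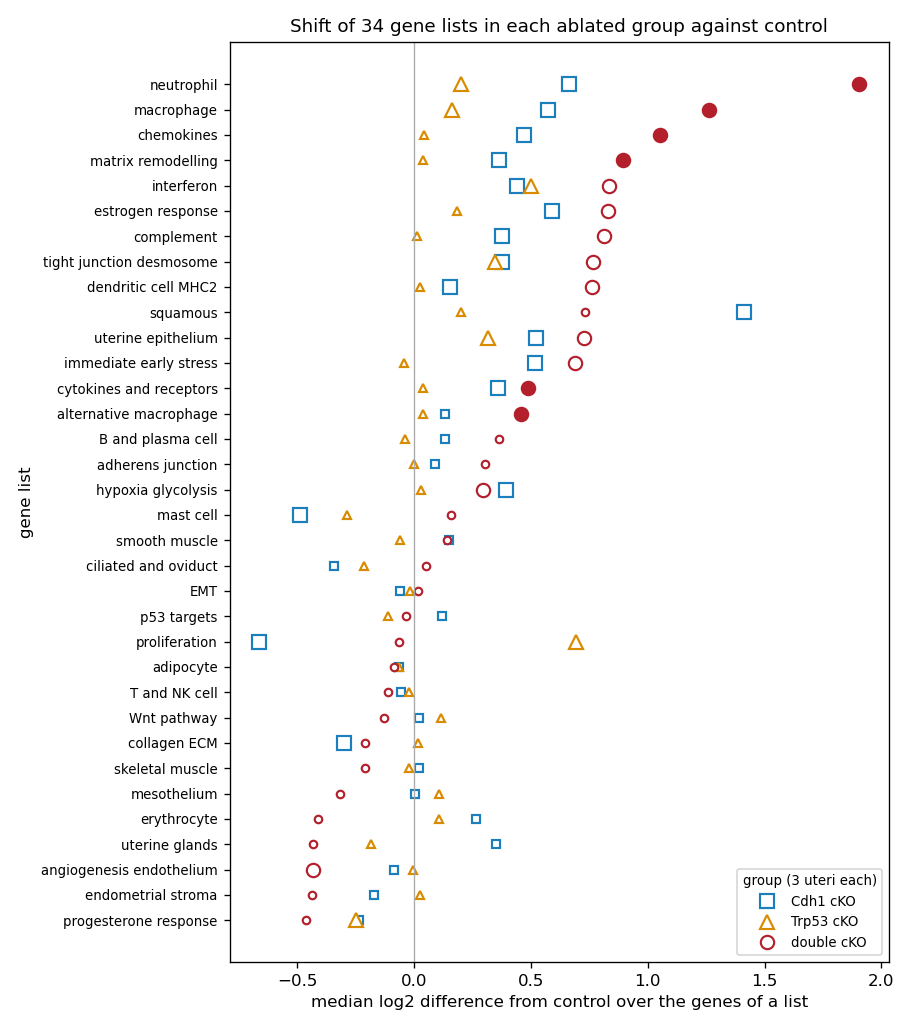
Median log2 difference from control of 34 gene lists in each ablated group, with large markers for lists called at the preset correlation and filled markers for those also called with an estimated correlation. Filled markers stand only at the neutrophil, macrophage, alternative macrophage, chemokine, cytokine and matrix remodelling lists of double cKO.

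The double cKO against the uteri labelled Cdh1 cKO asks what ablation of Trp53 adds to that of Cdh1, although Cdh1 was not lower in those uteri. The transcription factor gene Sox11 rose at least 18.9-fold (adjusted p = 0.00128) and H2-M2, a nonclassical MHC gene, at least 15.6-fold (adjusted p = 0.00121), followed by Cldn6, at least 12.5-fold higher, S100a9 at 3.43 ± 0.51 on the log2 scale (both adjusted p = 0.0140) and S100a8 at 3.30 ± 0.54 (adjusted p = 0.0249). Trim11 was at least 7.28-fold lower (adjusted p = 1.15e-04), the mitochondrial ribosome gene Mrpl55 fell by 0.999 ± 0.146 (adjusted p = 0.0125) and Nprl3, which encodes an inhibitor of mTORC1 signalling, fell by 1.16 ± 0.19 (adjusted p = 0.0272), with its other probe at -0.07. The clone-named gene 4933427D14Rik was the other that fell. Neutrophil genes rose by a median of 1.17, with 7 of 23 higher over all genes and 13 adjusted over the list alone (adjusted p = 3.56e-16, and 0.0181 with an estimated correlation), and the chemokine receptor gene Cxcr2 was at least 4.06-fold higher (adjusted p = 0.0107). Cytokines and receptors rose by a median of 0.42, with 4 of 31 higher over all genes and 11 adjusted over the list alone (adjusted p = 2.97e-08, and 0.0181 with an estimated correlation), among them Il1rn by 2.74 ± 0.25 (adjusted p = 6.90e-04). Matrix remodelling genes rose by a median of 0.30, with 2 of 24 higher over all genes and 7 adjusted over the list alone (adjusted p = 2.14e-05, and 0.0181 with an estimated correlation), namely Mmp12, at least 7.77-fold higher (adjusted p = 2.55e-04), and Mmp13 by 3.17 ± 0.32 (adjusted p = 0.00130). The other probes of Sox11 and Mmp13 differed by 2.58 and 0.003 on the log2 scale. The cytokine median was 0.28 without Cdh1 cKO replicate 2, and that of matrix remodelling was 0.64 and 0.68 without Cdh1 cKO replicate 2 or 3 and 0.49 and 0.45 without double cKO replicate 1 or 2. Macrophage genes had a median of 0.85, or 0.78 with dim genes at their bound, with 4 of 34 higher over all genes and 18 adjusted over the list alone (adjusted p = 6.13e-21, and 0.0522 with an estimated correlation). Limma called 60 genes, 56 higher and 4 lower, with 995 at an unadjusted p below 0.05, where chance gives 610, and 10.8% of genes did not overlap between groups, where chance gives 10%. The count was 34 without Cdh1 cKO replicate 1, 27 without double cKO replicate 3 and 7 in a model of only these 6 arrays, where Trim11, Il1rn and Mmp12 passed and Sox11, H2-M2, Cldn6, S100a9, S100a8, Mrpl55, Nprl3, Cxcr2 and Mmp13 did not. Cldn6, S100a8, Mrpl55, Nprl3 and Cxcr2 lost their calls without Cdh1 cKO replicate 1, and Cldn6, S100a9, S100a8 and Nprl3 without double cKO replicate 3. Of 34 lists, 15 were called, 3 of them with an estimated correlation, and 7 by fry.

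The double cKO against Trp53 cKO asks what ablation of Cdh1 adds to that of Trp53. Il1b rose at least 31.1-fold (adjusted p = 0.00138), Ffar4 at least 33.8-fold (adjusted p = 0.0123) and Sox11 at least 25.97-fold (adjusted p = 3.41e-04), and Mmp13 and Ppbp were at least 19.1-fold and 21.6-fold higher (adjusted p = 1.02e-04 and 0.00530). On the log2 scale, Arsj fell by 2.49 ± 0.33, the amino acid transporter gene Slc38a5 by 2.23 ± 0.30 (both adjusted p = 0.00365), Scd1, a gene of fatty acid desaturation, by 2.06 ± 0.31 (adjusted p = 0.00920), Aard by 2.28 ± 0.39 (adjusted p = 0.0175) and the stromal chemokine gene Cxcl12 by 2.18 ± 0.44 (adjusted p = 0.0394). Other probes differed by less on that scale, at 2.56 for Sox11, 0.11 for Mmp13, -0.58 for Arsj and -1.25 to -1.24 for Cxcl12. Cdh1 differed by -0.74 ± 0.45 and did not pass (adjusted p = 0.530). The same 6 lists held with an estimated correlation as against control. Neutrophil genes rose by a median of 1.84, or 1.498 with dim genes at their bound, with 11 of 23 higher over all genes and 15 adjusted over the list alone (adjusted p = 1.10e-17, and 0.0137 with an estimated correlation). Macrophage genes rose by a median of 1.09, with 9 of 34 higher over all genes and 24 adjusted over the list alone (adjusted p = 1.51e-25, and 0.0228 with an estimated correlation). Cytokines and receptors rose by a median of 0.74, with 12 of 31 higher over all genes and 15 adjusted over the list alone (adjusted p = 4.10e-12, and 0.00761 with an estimated correlation). Matrix remodelling genes rose by 0.65, chemokines by 0.90 and genes of alternatively activated macrophages by 0.55 (adjusted p at most 5.82e-05, and between 0.00761 and 0.0162 with an estimated correlation), and without Trp53 cKO replicate 2 the matrix remodelling median was 0.38. Proliferation genes had a median of -0.77, with 0 of 37 above 0 (adjusted p = 5.15e-05, and 0.590 with an estimated correlation), and without double cKO replicate 1 that call was lost (median -0.12, adjusted p = 0.651), while without double cKO replicate 2 the median was -1.17. Limma called 176 genes, 155 higher and 21 lower, with 1627 at an unadjusted p below 0.05, where chance gives 610, and 20.8% of genes did not overlap between groups, where chance gives 10%. The count was 68 without Trp53 cKO replicate 1, 101 without Trp53 cKO replicate 3 and 79 without double cKO replicate 3. Ffar4, Scd1, Aard and Cxcl12 lost their calls without Trp53 cKO replicate 1 or double cKO replicate 3, Aard also without Trp53 cKO replicate 3 or double cKO replicate 1, and Cxcl12 without any 1 of the 6 arrays or with the estrogen score as a covariate. Of 34 lists, 17 were called, 6 of them with an estimated correlation, and 11 by fry.

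The interaction asks whether loss of both genes changed expression by more or less than the sum of both single effects on the log2 scale. All 12 genes called lay above that sum in the model. Sox11 exceeded it by 5.09 ± 0.60 (adjusted p = 0.0246), with a difference from control of 3.97 in double cKO. Its other probe gave an interaction of 2.76. For Mmp12 the model gave 3.06 ± 0.34 (adjusted p = 0.0246). H2-M2, Mmp13 and Clec4n, a lectin receptor of myeloid cells, had values of 4.199 ± 0.579, 3.08 ± 0.46 and 2.94 ± 0.44 (adjusted p = 0.0406). Beyond the genes named by rule, all were looked at, since few passed. They were Cdkn2a, which encodes inhibitors of the cell cycle, at 2.84 ± 0.38, Il1rn at 2.46 ± 0.35, the coagulation factor genes F7 and F10 at 2.02 ± 0.29 and 1.84 ± 0.27, the stress kinase gene Mapk11 at 1.66 ± 0.23 and Cd300lf at 1.65 ± 0.25 (adjusted p between 0.0406 and 0.0463). Mmp12, Mmp13, F7 and F10 were not detected on any control or Trp53 cKO array, Il1rn on no control array and Cd300lf on none outside double cKO. The interactions of these 6 genes were computed against background signal, so they are neither sizes nor bounds, and the other probe of Mmp13 gave 0.14. H2-M2 was detected on 1 array of each group other than double cKO, Sox11 on 2 arrays of each single group, and Cdkn2a on 1 control array and 2 arrays of the uteri labelled Cdh1 cKO, so part of their values rests on background too. Casp4 differed in kind, at 2.33 ± 0.35 (adjusted p = 0.0406). Its differences from control were -1.02 and -1.20 in the single groups, where it was not called, and 0.11 in double cKO. In Trp53 cKO its other probes differed by only -0.58 to -0.51. Limma called 12 genes, with 583 at an unadjusted p below 0.05, where chance gives 610. The count was 0 without control replicate 1, control replicate 2, any of the Trp53 cKO replicates or double cKO replicate 3, 3 without Cdh1 cKO replicate 1 and 4 without its replicate 2, and 0 with the replicate number as a block. Of 34 lists, 9 were called, 0 with an estimated correlation and 2 by fry.

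The comparisons with control share their 3 control arrays. Vit was the 1 gene called against control both in the uteri labelled Cdh1 cKO and in double cKO, where 0.00820 falling genes would be shared by chance. Trim11 and 4933427D14Rik were the 2 genes called in both Trp53 cKO and double cKO, where 0.0164 would be shared by chance, and 0 genes were shared by the single groups, where chance gives 1.64e-04. Unchanged groups simulated with shared controls gave a mean overlap of 0, 0.01 and 0 genes. These groups were simulated without any pairing of arrays by number. Across genes, which are not independent replicates, the differences from control of the uteri labelled Cdh1 cKO and of double cKO correlated with r = 0.695, against 0.501 in simulated unchanged groups, with a covariance of 0.214 against 0.0585, an excess of 0.156. Those of Trp53 cKO and double cKO correlated with r = 0.478 (simulated 0.502, excess covariance 0.0371), and those of both single groups with r = 0.557 (simulated 0.502, excess covariance 0.0289). With 3 control arrays, no comparison can be given 2 controls of its own, so part of each excess may come from the shared arrays. Pairs of comparisons with no array in common give a view free of that. Of the 176 genes called in double cKO against Trp53 cKO, 91.5% had the same sign in the uteri labelled Cdh1 cKO against control, with a median of 0.54 in their direction against 1.61, and r over all genes was 0.467. Of the 60 genes called in double cKO against the uteri labelled Cdh1 cKO, 71.7% had the same sign in Trp53 cKO against control, with a median of 0.06 against 1.92, and r was 0.0560.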

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

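The tests of blood, tissue share, chromosome 11, p53 targets and epithelial RNA below were chosen only after the results they weigh were seen. Those of mislabelled uteri and of other splits of the arrays were set before. The estrogen score that the test of cycle stage uses was added as a covariate after the data had been seen.

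For 12 genes limma called an interaction, in which the effect of ablating 1 gene differs with the state of the other. In log2 units the values were 5.09 for Sox11, 4.199 for H2-M2, 3.08 for Mmp13, 3.06 for Mmp12, 2.94 for Clec4n, 2.84 for Cdkn2a, 2.46 for Il1rn, 2.33 for Casp4, 2.02 for F7, 1.84 for F10, 1.66 for Mapk11 and 1.65 for Cd300lf. Those of Mmp13, Mmp12, Il1rn, F7, F10 and Cd300lf were taken against at least 1 group in which the probe was not detected on any array, so they are neither sizes nor bounds, and the other probe of Mmp13 gave 0.14. Those of Sox11, H2-M2 and Cdkn2a rest on background in part. Of 100 splits of the 12 arrays into 4 groups of 3, 4 gave at least 12 genes, the real one included. That share is under 0.05, but other splits gave more genes than the real one. Such splits can place whole genotypes on opposite sides of the contrast, so that differences between genotypes enter their counts. Neither the share nor the higher counts therefore measure chance for the interaction, and chance is not excluded. Other values weaken the count. With the replicate number as a block 0 genes were called, and at an unadjusted p below 0.05 there were 583 genes where chance gives 610. The highest other split gave 914 genes. It set all 3 double cKO arrays against all 3 control arrays in the contrast, with each single group divided between both sides. The difference between double cKO and control thus entered its count. A split with 62 genes set all 3 double cKO arrays against all 3 Trp53 cKO arrays. The real split parted all 3 numbered pairs of control and Cdh1 cKO arrays, as 60 of the splits did, of which 2, the real one included, gave at least 12 genes, the highest other 62, while the split with 914 parted 2 pairs.

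The same term set apart 9 gene lists at the preset correlation, none with an estimated correlation, for which the smallest adjusted p was 0.0689. The median interaction was 1.12 for mast cell genes, 1.03 for neutrophil genes, 0.56 for macrophage genes, 0.50 for cytokines and receptors, 0.45 for complement genes, 0.44 for genes of alternatively activated macrophages and 0.25 for matrix remodelling. It was -0.23 for endothelial genes and -0.64 for mesothelium genes. Left out of the comparisons by gene were 3549 detected probes without exactly 1 gene symbol, of which 37 were called in double cKO against control, 25 higher and 12 lower, which is 1.04% against 2.73% of genes.

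Genes of macrophages, neutrophils and cytokines were higher in double cKO than in control. Blood left in the uteri is argued against, as the array medians of red blood cell genes differed by -0.295 ± 0.271 (SE) while those of neutrophil genes differed by 1.94 ± 0.28, and Hba-a1, the brightest red cell gene, differed by -0.48. A lower share of the main tissue, which would raise every other cell type alike, is argued against by T and NK cell genes at -0.0952 ± 0.167. That list was mixed, as Il7r rose and Nkg7 fell. Array medians of B and plasma cell and of mast cell genes differed by 0.223 ± 0.210 and 0.154 ± 0.317. Those of dendritic cell and MHC class II genes and of epithelium genes rose, by 0.668 ± 0.216 and 0.781 ± 0.317. Cycle stage, only as far as the estrogen score follows it, is argued against as the whole cause. With the score in the model the median of the 85 genes was 1.40, against 1.298 without it. By list, the median went from 1.90 to 1.53 for neutrophil, from 1.26 to 1.46 for macrophage and from 0.49 to 0.48 for cytokine genes. All 3 lists passed camera with an estimated correlation (adjusted p at most 0.0466). Called genes went from 36 to 29 as the median SE grew from 0.325 to 0.373. The stage itself is not given, and effects of stage that the score does not follow were not tested. A response to the combined ablation may remain as a hypothesis, but an infection or another cause tied to these 3 mice was not tested.

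Trim11, 4933427D14Rik and Mrpl55 were the 3 genes that fell with Trp53 ablation when both Trp53-ablated groups were set against the other uteri. All 3 lie on chromosome 11, as Trp53 does. By distance from Trp53 in assembly GRCm38.p6 they had ranks 272, 98 and 263 among the 1038 tested genes of that chromosome, so they are not its close neighbours. A stretch of another strain that reaches that far from the targeted allele could give this. Of 20 genes called, 6 lay on chromosome 11, these 3 and 3 that rose (2210407C18Rik, Cd300lf and Plek), where 8.51% of tested genes lie (Fisher's exact test, 1-sided, p = 0.00513), but without the 2 genes that prompted the test the p was 0.0607 and rested on 4 genes, of which 1 fell, which leaves that explanation open. Loss of p53 activity is open too: its targets had a median of -0.120 (camera p = 0.00363, and p = 0.0157 with an estimated correlation), in the direction that loss of p53 needs, but far smaller than the falls of these genes. Both cannot be told apart here, since either would go with the Trp53 genotype.

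Cdh1 was not lower in the uteri labelled Cdh1 cKO. The values go against control uteri carrying a wrong label, but 10 splits are too few to exclude it. The 176 genes called in double cKO against Trp53 cKO come from groups that share no array with these. Of them, 91.5% went the same way in these uteri against control, by a median of 0.54. The other 9 splits of the 6 arrays gave at most 83.5% and 0.26. More epithelial RNA, which could hide a fall in Cdh1 per cell, stays open. Cdh1 less the median of the epithelium genes was lower than in control by -0.588 ± 0.173 (SE), but it was lower still in Trp53 cKO, by -0.878 ± 0.157, where Cdh1 was not targeted. Probes outside the deleted exons, or deletion in a minority of the Cdh1-expressing cells, were not tested.

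With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Against control, the uteri labelled Cdh1 cKO gave 1 gene, and 3 of the splits gave at least as many, the highest other 11. Replicate numbers may pair these arrays. By those numbers, the highest other split kept 2 of the 3 pairs together. The 3 other splits that part all 3 pairs gave 0. Trp53 cKO gave 2 genes, at most 1 in other splits, and double cKO gave 333, at most 5 in others. For double cKO against the uteri labelled Cdh1 cKO the count was 60, at most 51 in other splits, and against Trp53 cKO it was 176, with 0 in others. In each of these last 4 comparisons the real split was the 1 with the largest count.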

How the results depend on the processing

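The estrogen score as a covariate and the block on only 6 arrays were added after the data had been seen; the other alternatives were planned. No named gene that was called reversed its direction at its chosen probe. Cdh1, which was not called, did in the uteri labelled Cdh1 cKO. Its difference from control went from 0.03 to -0.13 without control replicate 2 and to -0.07 without Cdh1 cKO replicate 3. So did medians of lists: with 1 array left out, 124 of 1020 medians of a list in a comparison changed sign. Of these, 7 were in lists called with or without that array. Against control, the median went from 0.15 to -0.04 for MHC class II and from -0.07 to 0.35 for adipocyte genes in the uteri labelled Cdh1 cKO, from 0.16 to -0.02 for macrophages in Trp53 cKO and from -0.06 to 0.56 for proliferation in double cKO. Against the uteri labelled Cdh1 cKO it went from -0.42 to 0.80 for squamous and from -0.01 to 0.25 for hypoxia genes, and against Trp53 cKO from 0.37 to -0.04 for interferon response, in double cKO. The processed matrix gave 333, 60, 175, 2, 1 and 12 genes in place of 333, 60, 176, 2, 1 and 12. Over their alternatives, the named genes of double cKO against control passed in 823 of 1070 cases, those against the uteri labelled Cdh1 cKO in 360 of 425, those against Trp53 cKO in 542 of 612 and those of the interaction in 64 of 154, and 29 of 63, 4 of 25, 23 of 36 and 0 of 7 genes passed in every one. Dim probes near the background limit the precision, since the signal over background decides them. Where a count changed below, the cause was not tested, except that models of fewer arrays have fewer degrees of freedom.

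For the uteri labelled Cdh1 cKO against control (1 gene), the count was 0 with an offset of 50, without background correction, without the detection filter, with the estrogen score, with only the arrays compared, with every named probe and with a replicate block on only these 6 arrays, and 3 with array weights; leaving out an array gave 0 to 38. For Trp53 cKO (2 genes) it was 6 with array weights, 1 with only the arrays compared, 4 with every named probe and 2 to 9 without an array. For double cKO against control (333) it was 4210 with array weights, 214 with the replicate block (205 of them shared), 171 with the estrogen score (125 shared) and 117 to 553 without an array. For double cKO against the uteri labelled Cdh1 cKO (60) it was 210 with array weights, 7 with only the arrays compared and 27 to 80 without an array. For double cKO against Trp53 cKO (176) it was 3672 with array weights, 104 with the replicate block and 68 to 139 without an array. For the interaction (12) it was 7 with an offset of 50, 4 without background correction, 7 with cyclic loess, 0 without the detection filter, 58 with array weights, 0 with the replicate block, 2 with the estrogen score, 4 with every named probe and 0 to 17 without an array. The iteration that finds array weights stopped before convergence, with weights from 0.34 to 11.7, and with them the Cdh1 difference of double cKO from control passed.

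For lists, an estimated correlation gave 0 for the uteri labelled Cdh1 cKO (17 at the preset), 0 for Trp53 cKO (7), 6 for double cKO against control (15), 3 against the uteri labelled Cdh1 cKO (15), 6 against Trp53 cKO (17) and 0 for the interaction (9). Fry gave 2, 0, 12, 7, 11 and 2 in that order. The interaction gave 8 to 14 lists without an array, 14 without double cKO replicate 2. Vit was no longer shared by the uteri labelled Cdh1 cKO and double cKO at an adjusted p below 0.01, where the overlap was 0 in place of 1. A chip block was not run because no chip is given, and a model of only the groups compared is the model used for the interaction.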

Other observations

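The comparison of all ablated uteri with control and the test of Pgr below were chosen only after the data were seen.

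In several lists that did not pass as a whole in double cKO against control, single genes passed. Of 21 T and NK cell genes, the interleukin 7 receptor gene Il7r rose by 1.71 ± 0.19 (adjusted p = 8.53e-04) and the T cell receptor-associated gene Cd6 rose at least 2.21-fold (adjusted p = 0.00230), while Nkg7, of cytotoxic granules, fell by 1.58 ± 0.36 (adjusted p = 0.0468), and fry found change in either direction (adjusted p = 3.11e-11). Adjusted over the list alone, 2 were higher and 3 lower. Of 26 collagens and matrix proteins, Col8a1, a short-chain collagen, rose at least 12.5-fold (adjusted p = 3.26e-04), or by 3.08 on the log2 scale at its other probe, and Col14a1 fell by 1.59 ± 0.27 (adjusted p = 0.0111), with 1 higher and 2 lower adjusted over the list alone (median -0.21, adjusted p = 0.492). Of 13 adipocyte genes, the lipid synthesis genes Thrsp and Scd1 fell, the latter by 1.70 ± 0.31 (adjusted p = 0.0188), and Gpd1 rose at least 2.39-fold (adjusted p = 0.0379), with a median of -0.09 (adjusted p = 0.815). Of 26 stromal genes, the adhesion gene Vcam1 rose by 1.02 ± 0.24 (adjusted p = 0.0492), with 2 higher and 3 lower adjusted over the list alone (median -0.44, adjusted p = 0.323). Of 14 gland genes, the water channel gene Aqp5 rose by 2.39 ± 0.52 (adjusted p = 0.0364) and Wfdc3 was at least 4.83-fold lower (adjusted p = 0.0463), with a median of -0.43 (adjusted p = 0.805). Of 10 ciliated and oviduct genes, Tppp3 fell by 2.09 ± 0.44 (adjusted p = 0.0324), while the list had a median of 0.05 and a mean of -0.24 (adjusted p = 0.953). The median of that list was 1.14 on double cKO replicate 1, and -0.14 and -0.35 on the others of this group. On replicate 1 the log2 signal of Ovgp1 was 13.20 and that of the cilium gene Rsph1 9.17, while the other double cKO arrays had 5.43 and 5.79 for Ovgp1 and 6.84 and 6.82 for Rsph1. The control arrays had 10.39 to 11.95 for Ovgp1 and 7.26 to 7.79 for Rsph1. Il7r, Cd6 and Col8a1 passed in every alternative, while Scd1, Nkg7, Gpd1, Vcam1, Aqp5, Wfdc3 and Tppp3 lost their calls without control replicate 1 or 2, and Col14a1 without control replicate 2. With the estrogen score as a covariate, these 8 and Thrsp were not called. The differences of Vcam1, Tppp3 and Nkg7 were then 1.02 ± 0.31, -1.97 ± 0.57 and -1.35 ± 0.46, close to those without the score, while their SE had been 0.24, 0.44 and 0.36. Those of Col14a1, Scd1 and Aqp5 were smaller with it, at -1.31 ± 0.32, -1.22 ± 0.33 and 1.64 ± 0.56, where the model without the score gave -1.59 ± 0.27, -1.70 ± 0.31 and 2.39 ± 0.52. Wfdc3, Gpd1 and Thrsp were at background on some arrays, and their sizes were not compared.

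Other lists gave no call in double cKO against control, or a call that single arrays decided. Hypoxia and glycolysis genes had a median of 0.30 (adjusted p = 0.0108, and 0.551 with an estimated correlation), and without double cKO replicate 1 the adjusted p was 0.308. The median was 0.73 for squamous genes, or 0.24 with dim genes at their bound (adjusted p = 0.0572), 0.02 for genes of epithelial-mesenchymal transition (adjusted p = 0.962), 0.14 for smooth muscle (adjusted p = 0.395), -0.46 for progesterone response (adjusted p = 0.289), -0.32 for mesothelium (adjusted p = 0.230) and -0.21 for skeletal muscle (adjusted p = 0.172). Median and mean differed in sign for B and plasma cells at 0.36 and -0.02 (adjusted p = 0.484), mast cells at 0.16 and -0.004 (adjusted p = 0.615) and the Wnt pathway at -0.13 and 0.19 (adjusted p = 0.484), and the camera direction of red blood cell genes was up although their median was below 0. Without double cKO replicate 1 the squamous list passed (adjusted p = 0.0318), and without control replicate 3 that of progesterone response did (adjusted p = 0.0413). In the uteri labelled Cdh1 cKO, genes of tight junctions had a median of 0.37, of interferon response 0.44, of matrix remodelling 0.36, of chemokines 0.47, of complement 0.38, of estrogen response 0.59, of hypoxia 0.39, of MHC class II 0.15, of collagens -0.30 and of mast cells -0.49 (adjusted p at most 0.0268, and at least 0.0918 with an estimated correlation). Of these, the calls for chemokines, complement and MHC class II were lost without control replicate 3, those for complement, MHC class II, collagens and mast cells without Cdh1 cKO replicate 2, those for estrogen response, hypoxia and mast cells without its replicate 3, and that for mast cells also without control replicate 1. Single arrays also moved medians that stayed called. The tight junction median was 0.22 and 0.67 without control replicate 1 or 3, that of interferon response 0.71 and 0.25 without Cdh1 cKO replicate 1 or 3, that of estrogen response 0.35 and 0.95 without control replicate 2 or 3, and that of collagens -0.58 without Cdh1 cKO replicate 3. That of MHC class II was 0.29 and 0.34 without control replicate 1 or 2, and 0.24 and 0.27 without Cdh1 cKO replicate 1 or 3. In Trp53 cKO, genes of macrophages had a median of 0.16, of neutrophils 0.20, of epithelium 0.31 and of tight junctions 0.35 (adjusted p at most 0.0398, and 0.764 with an estimated correlation). The macrophage call was lost without control replicate 3 or Trp53 cKO replicate 3, the neutrophil call without control replicate 2, the epithelium call without control replicate 1 or 2, and the tight junction call without any 1 of the 6 arrays but control replicate 3 and Trp53 cKO replicate 2. Other medians were larger: 0.36 for macrophages without control replicate 1 and 0.26 without Trp53 cKO replicate 1 or 2, and 0.64 for epithelium and 0.62 for tight junctions without control replicate 3.

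Set together against control, the 9 ablated uteri differed in 21 genes, 17 higher and 4 lower. Il1rn, which was not detected on any control array, was higher, as was S100a8, by 3.25 ± 0.44, the peptide transporter gene Slc15a3 by 1.57 ± 0.21 and Nupr1 by 1.63 ± 0.21, while Vit was lower. All 21 were also called in double cKO alone. For 19 of them the means of all 3 ablated groups lay on the same side of control, and for 7 all 9 ablated uteri lay beyond all controls. In Trp53 cKO, Mmp12 and Mmp13 were at background as in control, and in the uteri labelled Cdh1 cKO, Trim11 and 4933427D14Rik were at 7.71 and 8.05, not lower than in control at 7.13 and 7.91. A change shared by every ablated uterus, whichever gene was targeted, was looked for in Pgr, the progesterone receptor gene, since a recombinase inserted at a gene could lower it. Pgr had a log2 signal of 9.15 ± 0.21 (SD, n = 3) in control and 8.26 ± 0.47 (n = 9) in ablated uteri, a difference of -0.89, and 9 of 9 ablated uteri lay below all controls (exact 2-sided permutation p = 0.0136 over 220 splits). As Pgr was picked for being lower in all 3 ablated groups, that p restates what was seen and lends the explanation no support. It also ignores any pairing of control and Cdh1 cKO arrays by number. Picked from 12194 genes it did not pass in limma (adjusted p = 0.208), and 117 genes lay below all controls in every ablated uterus where chance gives 55.4, so that Pgr is 1 of many and the explanation stays open. The recombinase is not given in the sources used here, and a common background of the control mice was not tested.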
